A study of Cucumis melo with 60 samples.

How the data were processed

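Pulp of melon fruit (Cucumis melo) of the cultivars Jiashi and 86-1 was sampled after inoculation with the fungus Alternaria alternata, a cause of black spot rot in stored fruit, or with sterile water as the control. Fruit was sampled on days 0, 6, 12, 18 and 24 of storage, with 3 libraries for each cultivar, treatment and day. Per the labels' protocols, RNA was treated with DNase I, selected with oligo(dT) beads, copied from random hexamers and sequenced as single-end reads on the BGISEQ-500 platform. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, without saying what each was used for. The genome build and the gene annotation are not given in the sources used here.

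The authors deposited 1 table of FPKM values, with 29502 genes and 60 libraries, rounded to 2 decimals. Read counts were not used here, so no count model was fitted. Each of the 60 columns was matched to its sample through the name that the labels give it, and groups came from the labels alone. No 2 libraries held identical values, and the highest correlation between any pair of libraries was 0.992.

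Gene identifiers were used as the table gives them. A table of 28628 RefSeq genes of the USDA_Cmelo_AY_1.0 assembly matched 0 of the identifiers, so no gene names or functions are given. The 30 gene lists planned before the data were examined were defined by gene descriptions and were void for that reason. The rule for naming genes fell back, as planned, to 2 identifiers that rose and 2 that fell in each of the comparisons of means, storage and cultivars. These had the largest log2 differences among genes at adjusted p under 0.05 with a mean of at least 5 FPKM on the higher side. For the infection means, the sign also had to be the same on all 4 days. Counts of libraries on the side of a change describe these genes and are no separate support, since the same libraries picked them.

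Relative depth was read from the low values. In 1567 rarely seen genes, values fell on steps that correspond to whole reads. In each library, the most frequent step relative to the gene's usual lowest value gave what 1 read was worth. In the 48 libraries of days 0 to 18, 1 read was worth 0.90 to 1.46 times the median of those libraries. In the 12 libraries of day 24 it was worth 1.46 to 7.21 times that median, so these libraries were shallower and their low values less precise. The absolute number of reads is unknown. The steps were tested on simulated reads of 20000 genes. The largest error was 10.9% for libraries with depths like those of days 0 to 18 and 3.65% for depths like those of day 24. All simulated libraries shared the same expected levels, so the effect of unlike numbers of detected genes on the steps was not tested. FPKM sums per library ranged from 598323 to 794872.

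Values were analysed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries were kept (23942 genes). Fold changes are on that scale, which understates the change of genes with low values. All 60 libraries entered 1 linear model of 20 group means in limma 3.58.1 (R 4.3.3), with a mean-dependent prior for the spread. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at adjusted p under 0.05. The labels do not say that the 3 libraries of a group came from separate fruit, so p-values measure only the spread between these samples, which may be technical.

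The comparisons, the test and the alternatives were fixed before the data were examined: a pseudocount of 0.1, no filter, a filter on a mean of at least 5 FPKM, median-ratio scaling of each library, the replicate number as a block, library weights, a fit of only the groups compared, and each library left out in turn. The default estimation of library weights did not converge, and the gene-by-gene method was used in its place. Alternatives without day 24, without day 12 and without 2 libraries that stood apart were added after the data were seen. These 2 correlated below 0.9 with each other library of their group (highest 0.824 and 0.879). That rule replaced a rule on the mean correlation, which had picked 4 libraries, and was set after that result was seen. Median-ratio factors ranged from 0.73 to 1.26. This scaling moved the median log2 difference over all genes by more than 0.1 in 2 comparisons, from 0.10 to −0.05 for infection in Jiashi at day 18 and from 0.14 to 0.27 for storage in Jiashi.

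Calls on day 24 rest on a spread pooled over all groups, although day 24 controls varied more. The model was tested on simulated data of the 23942 genes in which 200 genes were changed. The changed genes were drawn from those above a low mean level. Noise was independent for each gene and library, so shifts of whole libraries were not simulated and false calls from them not measured. In the real data, regrouping the Jiashi libraries of day 6 against their labels called as many as 3326 genes. With the same spread in every group, the mean infection comparison in Jiashi recovered 88.1% of genes changed by 1 log2 unit and 94.0% of those changed by 2, with 20 false calls. The comparison in Jiashi at day 18 recovered 49.3% and 91.0%, with 13 false calls. With the spread observed in each group, false calls rose to 1746 for infection in Jiashi at day 24, 324 for infection in 86-1 at day 24, 576 for storage in Jiashi and 321 for storage in 86-1. The fit of only the groups compared gave 2, 9, 4 and 9 false calls in the same simulations, but recovered fewer changed genes. With the observed spread, the fit of all libraries gave 66 false calls for the mean infection comparison in Jiashi and 7 for that in 86-1. It gave 26 for the difference of responses, 41 for infection in Jiashi at day 12, 0 at day 18 and 41 for the cultivars. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.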

Results

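Transcript levels were measured in melon pulp in 60 libraries that fell into 20 groups of 3, one for each combination of cultivar (Jiashi or 86-1), treatment (inoculated with Alternaria alternata, called infected here, or water control) and day of storage (0, 6, 12, 18 or 24). Libraries of days 0 to 18 had 14868 to 19080 genes at 1 FPKM or more (median 16009, n = 48), and those of day 24 had 14862 to 23003 (median 17113, n = 12). The spread between libraries of a group, as the residual SD of log2 values, was 0.96 in Jiashi controls and 0.83 in 86-1 controls at day 24. In the other 18 groups it was 0.25 to 0.69.

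**Figure D1:**
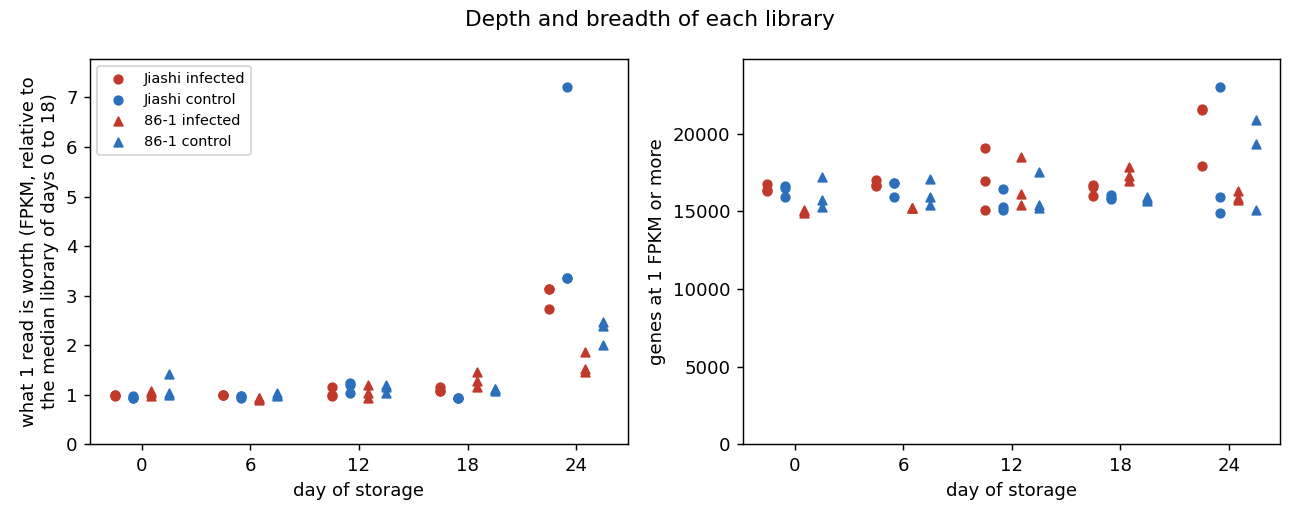
Depth and breadth of the 60 libraries. The left panel shows what 1 read was worth in FPKM relative to the median library of days 0 to 18, and the right panel the number of genes at 1 FPKM or more, against day of storage (points are libraries, red infected, blue control, circles Jiashi, triangles 86-1). At day 24, 1 read was worth 1.46 to 7.21 times the median, and the number of genes reached 23003.

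The first 2 principal components held 31.9% and 16.3% of the variance. All 12 libraries of day 24 lay above all others on component 1, those of day 18 lay mostly above those of days 0 to 12, and days 0, 6 and 12 overlapped. On component 2, the 3 control libraries of day 24 spread widely in each cultivar, from −132.8 to 61.4 in Jiashi and from −60.9 to 84.1 in 86-1.

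**Figure D2:**
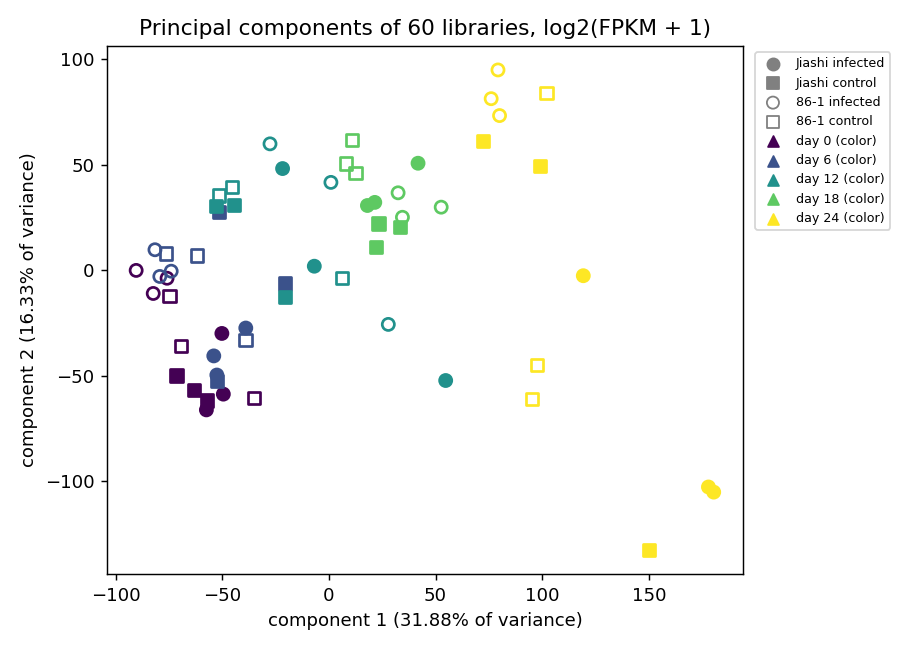
Principal components 1 (31.9% of variance) and 2 (16.3%) of log2(FPKM + 1) in 60 libraries. Color gives the day of storage, filled symbols are Jiashi, open symbols 86-1, circles infected and squares control. On component 1 the libraries of day 24 lie above all others, while days 0, 6 and 12 overlap.

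Infected and control fruit were compared on each day to ask which transcripts responded to the fungus and when. In Jiashi, 178 genes differed at day 0 (89 higher in infected fruit, 89 lower), 17 at day 6 (6 higher, 11 lower; 2 to 1757 when 1 library was left out, the highest without control replicate 1) and 470 at day 12 (284 higher, 186 lower). At day 18, 3170 genes differed (2335 higher, 835 lower), and at day 24, 7673 (4832 higher, 2841 lower). Day 18 and day 24 share no library, and 649 genes were higher at both, against 471 for independent lists. Another 394 were lower at both, against 99.1, and 288 went opposite ways, against 446. Between day 12 and day 18, 42 genes were higher at both, against 27.7, and 57 went opposite ways, against 28.0. Between day 12 and day 24, 51 were higher at both, against 57.3, and 134 went opposite ways, against 71.2. Across genes, day 6 correlated with day 18 at −0.38. Median-ratio scaling turned the day 18 split to 1083 higher and 1660 lower and the day 12 split to 191 higher and 262 lower, so the balance of directions was not fixed by these data. In a fit of only the 6 libraries compared, the counts were 2 at day 0, 0 at days 6 and 12 (3638 genes at unadjusted p under 0.05 in the fit of all libraries at day 12, and 2063 at day 6), 5147 at day 18 and 2526 at day 24.

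**Figure D3:**
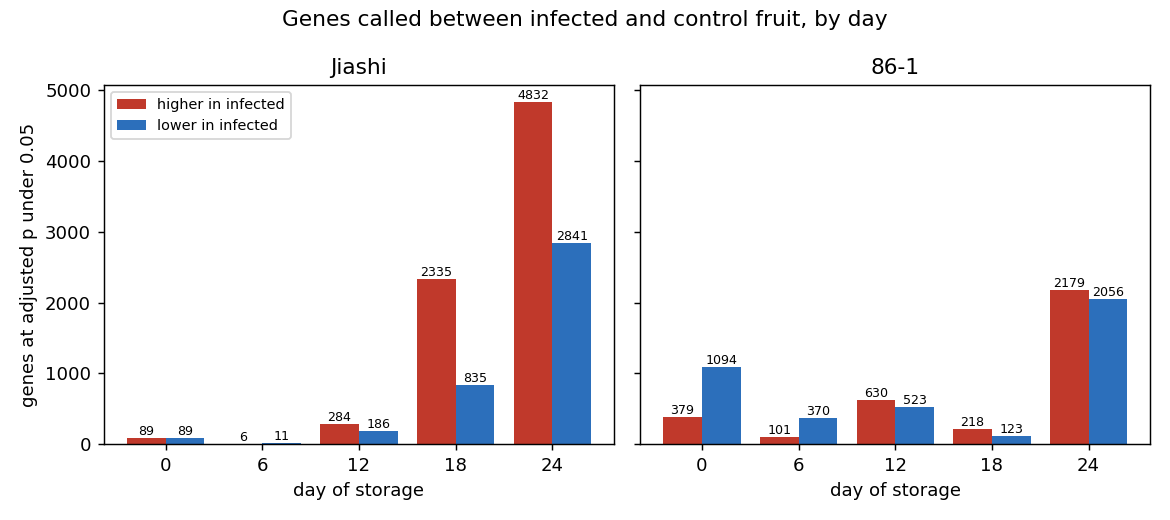
Genes at adjusted p under 0.05 between infected and control fruit on each day of storage in Jiashi (left) and 86-1 (right), with red bars for genes higher in infected fruit and blue bars for genes lower. In Jiashi the counts rose to 4832 higher and 2841 lower at day 24. In 86-1, 1094 genes were lower in fruit labelled infected at day 0.

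Over days 6 to 24 in Jiashi, MELO3C013292.2 and MELO3C006465.2 had the largest increases in infected fruit among called genes with the same sign on all 4 days and at least 5 FPKM. MELO3C013292.2 was higher by 2.68 log2 units (SE 0.65, adjusted p = 0.0037), in 10 of 12 infected libraries. Its level in infected fruit was 9.19 ± 2.67 FPKM at day 12 (SD, n = 3) against 0.64 ± 0.99 in controls, and 878.1 ± 1343 at day 18 against 4.48 ± 3.87. At day 24 controls had reached 927.9 ± 800.9, against 2007 ± 412.5 in infected fruit. MELO3C006465.2 was higher by 2.37 (SE 0.43, adjusted p = 0.000173), also in 10 of 12 libraries, with 66.7 ± 71.9 FPKM against 0.58 ± 0.26 at day 18 and 209.8 ± 11.3 against 14.33 ± 15.02 at day 24. MELO3C030151.2 was lower by −1.56 (SE 0.20, adjusted p = 4.65e-07), in 11 of 12 libraries. This came almost wholly from day 24, at 0.31 ± 0.53 FPKM in infected fruit and 66.1 ± 37.9 in controls. At day 24 in 86-1 it went the other way, at 53.6 ± 57.0 FPKM in infected fruit and 0.97 ± 0.84 in controls (log2 difference 4.40, adjusted p = 1.75e-10). MELO3C007438.2 was lower by −1.22 (SE 0.41, adjusted p = 0.0405), in 10 of 12 libraries, with 155.7 ± 117.2 FPKM against 785.0 ± 333.7 at day 18.

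In this mean over days 6 to 24 in Jiashi, 3408 genes differed (2282 higher in infected fruit, 1126 lower). With median-ratio scaling 3512 differed, 1492 higher and 2020 lower. Without day 24 the count was 258, and of the 4 named genes only MELO3C013292.2 kept its call (adjusted p = 0.0328, from 0.000126 to 0.0328 over 10 alternatives). The log2 difference of MELO3C006465.2 was then 1.74 (adjusted p = 0.0676, from 8.1e-07 to 0.0676) and that of MELO3C007438.2 was −1.16 (0.272, from 0.0156 to 0.272), close to its value with day 24. That of MELO3C030151.2 shrank to −0.24 (0.778, from 1.02e-08 to 0.778). Without Jiashi control day 24 replicate 3 the count was 7934, and leaving out single libraries ended the call of MELO3C007438.2 in 11 of 24 fits.

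**Figure D4:**
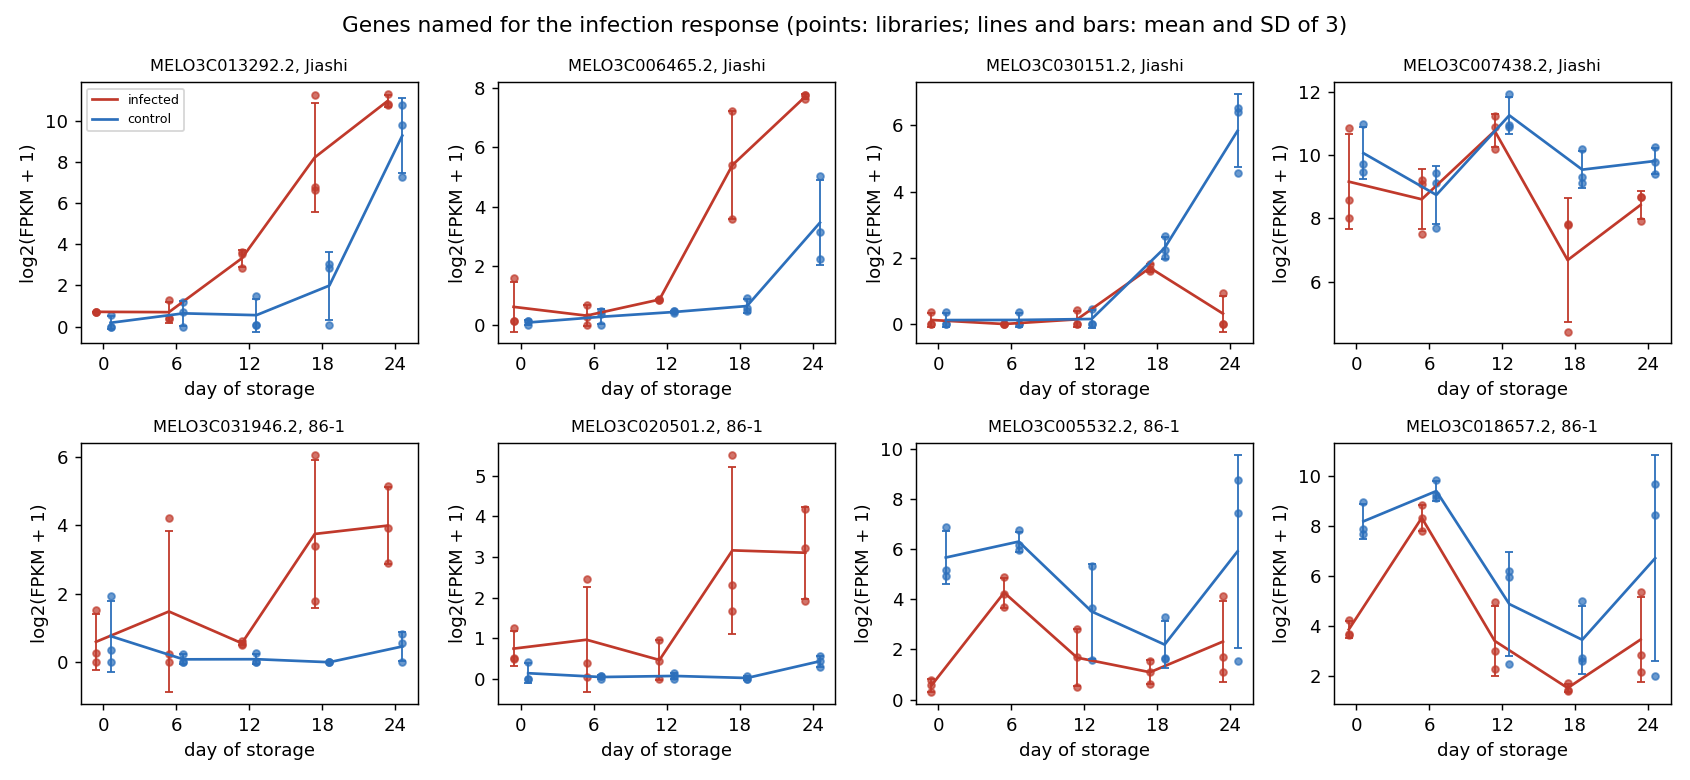
Levels of the 4 genes named for infection in Jiashi (top) and the 4 named for infection in 86-1 (bottom), as log2(FPKM + 1) against day of storage. Points are libraries, and lines with bars are means and SD of 3 (red infected, blue control). MELO3C006465.2 reached 209.8 FPKM in infected Jiashi fruit at day 24 against 14.3 in controls, while MELO3C005532.2 was already lower at day 0 in 86-1.

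At days 0, 6 and 18, infected and control 86-1 libraries did not overlap in the number of genes at 1 FPKM or more. It was 14868 to 15054 in infected libraries against 15300 to 17227 in controls at day 0. At day 6 it was 15196 to 15225 against 15380 to 17090, and at day 18 16922 to 17886 against 15657 to 15928. Calls on these days are not separated from that number. In 86-1 the groups already differed at day 0, with 1473 genes called (379 higher in infected fruit, 1094 lower). The counts were 471 at day 6 (101 higher, 370 lower), 1153 at day 12 (630 higher, 523 lower), 341 at day 18 (218 higher, 123 lower) and 4235 at day 24 (2179 higher, 2056 lower). Median-ratio scaling gave 685 higher and 656 lower at day 0, 278 and 189 at day 6, 447 and 688 at day 12, 177 and 188 at day 18, and 1598 and 2363 at day 24. In a fit of only the 6 libraries compared, limma called 1570 genes at day 0, 56 at day 6, 200 at day 12, 3 at day 18 and 0 at day 24, where the fit of all libraries had 8588 at unadjusted p under 0.05.

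Over days 6 to 24 in 86-1, MELO3C031946.2 and MELO3C020501.2 rose most in infected fruit by the same rule. MELO3C031946.2 was higher by 2.29 log2 units (SE 0.44, adjusted p = 0.0023), in 11 of 12 libraries, at 25.9 ± 34.6 FPKM at day 18 (SD, n = 3), when it was listed at 0 in all controls, and 18.4 ± 14.5 against 0.41 ± 0.38 at day 24. It was also called in Jiashi at day 18, at 128.4 ± 37.4 FPKM against 1.21 ± 0.73 (log2 difference 5.88, adjusted p = 2.48e-05), but not at day 24, at 5.75 ± 1.85 against 5.77 ± 7.33 (0.72, adjusted p = 0.553), nor at day 6 (−0.32, adjusted p = 1). MELO3C020501.2 was higher by 1.78 (SE 0.39, adjusted p = 0.00707), in 11 of 12 libraries, and in Jiashi at day 18 it stood at 53.1 ± 7.54 FPKM against 0.080 ± 0.052 (log2 difference 5.64, adjusted p = 5.3e-06). MELO3C005532.2 was lower by −2.14 (SE 0.46, adjusted p = 0.00633), in 12 of 12 libraries, and MELO3C018657.2 by −1.93 (SE 0.49, adjusted p = 0.0232), in 11 of 12. Both were lower in the infected group already at day 0, with 0.48 ± 0.26 FPKM against 60.7 ± 49.1 for MELO3C005532.2 (adjusted p = 0.000368) and 13.97 ± 3.597 against 317.2 ± 164.9 for MELO3C018657.2 (adjusted p = 0.00465).

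The mean over days 6 to 24 in 86-1 differed in 606 genes (361 higher in infected fruit, 245 lower), or 626 with median-ratio scaling (287 higher, 339 lower). Without day 24 the count was 101, and none of the 4 named genes passed (adjusted p from 0.0947 to 0.324). Their log2 differences were then 1.87 for MELO3C031946.2, 1.48 for MELO3C020501.2, −1.66 for MELO3C005532.2 and −1.49 for MELO3C018657.2, so the lost calls do not show that the differences came from day 24 alone. In the fit of only the groups compared, MELO3C005532.2 (adjusted p = 0.0996, from 8.32e-08 to 0.18 over 10 alternatives) and MELO3C018657.2 (0.175, from 1.57e-07 to 0.324) did not pass, and the count was 395. It was 1970 without 86-1 control day 24 replicate 2, 356 without 86-1 control day 24 replicate 1 and 299 without 86-1 infected day 18 replicate 2.

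The mean responses of both cultivars share no library. Of their calls, 103 genes were higher in both, against 34.4 for independent lists, and 44 were lower in both, against 11.5, while 26 went opposite ways, against 40.3. Across all 23942 genes, which are not independent replicates, the correlation of the responses was 0.12. Day by day, the correlation was 0.23 at day 6, 0.37 at day 12, 0.16 at day 18 and −0.29 at day 24. At day 12, 39 genes were higher in both, against 7.47 for independent lists, and 31 were lower in both, against 4.06. Another 6 went opposite ways, against 11.1. In both cultivars, infected replicate 2 of day 12 had the most genes at 1 FPKM or more in its group (19080 in Jiashi, 18518 in 86-1). The agreement at day 12 is not separated from these libraries. At day 24, 474 genes were higher in both, against 440, 104 were lower in both, against 244, and 998 went opposite ways, against 674. In these libraries the infected minus control difference in the mean number of genes at 1 FPKM or more was 2429 in Jiashi and −2448 in 86-1. The opposite calls of day 24 are not separated from that.

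The difference between the responses was tested directly, to ask which genes responded differently in each cultivar, and 817 genes passed (470 with the higher response in Jiashi, 347 with the higher response in 86-1). Median-ratio scaling gave 401 and 660. MELO3C028362.2 had a response 2.67 log2 units higher in Jiashi (SE 0.27, adjusted p = 1.16e-08). It was at 17.7 ± 8.38 FPKM in 86-1 controls and 0.91 ± 0.78 in infected 86-1 fruit at day 6 (SD, n = 3), 24.9 ± 5.45 and 1.74 ± 0.94 at day 18, and 23.4 ± 3.81 and 0.72 ± 1.24 at day 24. The same gap was present at day 0, at 16.9 ± 3.57 and 0.52 ± 0.53 FPKM. At day 12 it was the other way round, at 2.21 ± 0.13 in controls and 9.21 ± 5.15 in infected fruit (adjusted p = 0.0122). In Jiashi the response did not pass (log2 difference 0.40, SE 0.19, adjusted p = 0.153).

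MELO3C010323.2 had a response 2.59 units higher in Jiashi (SE 0.67, adjusted p = 0.023), where it stood at 4966 ± 1187 FPKM in infected fruit and 536.3 ± 410.1 in controls at day 24. MELO3C001614.2 had a response lower in Jiashi by −4.22 (SE 1.099, adjusted p = 0.0232), and neither cultivar passed alone (adjusted p = 0.0817 in Jiashi and 0.113 in 86-1). The 86-1 groups already differed at day 0, at 39.4 ± 20.4 FPKM in infected fruit and 0.08 ± 0.13 in controls (log2 difference 5.09, adjusted p = 0.04). MELO3C033636.2 had a response lower in Jiashi by −2.86 (SE 0.38, adjusted p = 5.23e-06). At day 24 it was at 2.69 ± 0.24 FPKM in infected Jiashi fruit against 123.4 ± 47.8 in controls, and at 111.5 ± 70.5 against 2.37 ± 2.66 in 86-1. Without day 24, 86 genes passed the test of the difference and MELO3C028362.2 alone of the 4 kept its call (adjusted p = 5.75e-05, from 2.55e-12 to 5.75e-05 over 10 alternatives). The difference was then 2.92 for MELO3C010323.2 (adjusted p = 0.0829, from 0.00076 to 0.134), above its value with day 24, −2.62 for MELO3C001614.2 (0.534, from 0.000438 to 0.534) and −0.45 for MELO3C033636.2 (0.958, from 5.79e-09 to 0.958). The count was 4019 without Jiashi control day 24 replicate 3, 1633 without 86-1 control day 24 replicate 2, 1462 without Jiashi infected day 24 replicate 2 and 1281 without Jiashi infected day 12 replicate 1.

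Water controls of day 24 and day 0 were compared to describe storage without the fungus. In Jiashi controls 10530 genes differed (4608 higher at day 24, 5922 lower), and in 86-1 controls 10150 (5143 higher, 5007 lower). Median-ratio scaling gave 5837 higher and 5072 lower in Jiashi. In a fit of only the 6 libraries compared, 6953 genes differed in Jiashi and 4891 in 86-1. The cultivars share no library here. In both, 3107 genes rose, against 990 for independent lists, and 4038 fell, against 1238, while 107 went opposite ways, against 2236. The correlation across genes was 0.78.

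In Jiashi controls, MELO3C006965.2 rose from 1.55 ± 0.64 FPKM at day 0 to 16160 ± 2285 at day 24 (SD, n = 3, log2 difference 12.66, SE 1.07, adjusted p = 4.3e-13), and stood at 3690 ± 992.2 at day 18. MELO3C026923.2 rose from 0.59 ± 0.17 to 4579 ± 1824 (log2 difference 11.42, SE 0.90, adjusted p = 6.91e-14). MELO3C015184.2 fell from 196.5 ± 110.7 to 0.55 ± 0.25 (log2 difference −6.87, SE 0.57, adjusted p = 2.04e-13). MELO3C035520.2 was at 125.5 ± 85.4 at day 0 and listed at 0 in all 3 libraries at day 24 (adjusted p = 5.78e-05), but was still at 164.2 ± 40.9 at day 18. It was also listed at 0 in the other 9 libraries of day 24, infected and control, in both cultivars. In 86-1 controls, MELO3C009383.2 rose from 1.81 ± 1.75 to 7334 ± 12120 (log2 difference 8.75, SE 1.28, adjusted p = 3.02e-07). Its log2 difference was 6.60 without control day 24 replicate 2, a library that stood apart, and 10.45 without control day 24 replicate 1. MELO3C030787.2 rose from 2.84 ± 2.04 to 1359 ± 41.1 (log2 difference 8.62, SE 0.64, adjusted p = 2.35e-14). MELO3C020810.2 fell from 211.0 ± 37.5 to 0.84 ± 0.71 (log2 difference −6.90, SE 0.38, adjusted p = 1.17e-17), and MELO3C021249.2 from 692.1 ± 345.1 to 11.6 ± 9.60 (log2 difference −5.94, SE 0.68, adjusted p = 1.33e-09). All 3 libraries of day 24 lay on the side of the change for each of these 8 genes, which were picked for large differences in these same libraries.

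The day 24 libraries were shallower than those of day 0. In the 12 libraries of day 24 together, 199 genes lay below and 74 above every library of the other days, against 0 and 2 for day 18 and 53 and 45 for day 0. The labels give no preparation or sequencing batch, so a batch at day 24 was neither shown nor excluded, and the counts at day 24 are not separated from it. With day 18 in place of day 24, 7398 genes differed in Jiashi and 6514 in 86-1, against the same day 0 libraries. MELO3C035520.2 was the only one of the 8 that did not pass at day 18 (log2 difference 0.60, adjusted p = 0.889, from 6.41e-06 to 0.889 over 9 alternatives). At day 18, 2004 genes had risen in both cultivars, against 411 for independent lists, and 2384 had fallen in both, against 585.

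Jiashi and 86-1 controls were compared over all 5 days to describe the cultivars themselves. Of 6589 genes that differed, 2803 were higher in Jiashi and 3786 in 86-1, and median-ratio scaling gave 3532 and 3199. With the replicate number as a block within each cultivar, 3908 genes differed (2062 and 1846). That fit set the cultivars against each other at unlike replicate numbers, not at their means, so its count does not bear on the 6589. MELO3C033614.2 was at 36.0 ± 18.7 FPKM in Jiashi and 0.077 ± 0.177 in 86-1 (SD, n = 15, log2 difference 4.91, SE 0.16, adjusted p = 4.76e-27). MELO3C005215.2 was at 501.4 ± 328.9 in Jiashi and 22.04 ± 10.95 in 86-1 (log2 difference 4.22, SE 0.27, adjusted p = 7.81e-17). MELO3C035119.2 was at 0.042 ± 0.163 in Jiashi and 18.0 ± 9.42 in 86-1 (log2 difference −4.05, SE 0.12, adjusted p = 5.51e-29), and MELO3C023067.2 at 38.3 ± 33.3 and 669.5 ± 641.9 (log2 difference −4.07, SE 0.32, adjusted p = 1.31e-13). Each of these 4 genes differed in its direction in 15 of 15 Jiashi libraries, from which, with the 86-1 libraries, they had been picked.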

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

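The tests on the number of genes at day 24 and on the labels of day 12, and the adjustment over splits, were chosen after the results were seen. A direct test of the difference between the cultivars' infection responses, which singled these results out, passed for 817 genes. Among the named ones, the response was higher in Jiashi by 2.67 log2 units for MELO3C028362.2 and 2.59 for MELO3C010323.2, and lower by −4.22 for MELO3C001614.2 and −2.86 for MELO3C033636.2. This test does not subtract day 0. At day 0 infected and control fruit differed by −3.60 in 86-1 and −0.44 in Jiashi for MELO3C028362.2, and by 5.09 and −2.54 for MELO3C001614.2. For these 2 genes the gap between cultivars was thus present before day 6. For MELO3C010323.2 the day 0 values were 0.08 and 1.74, and for MELO3C033636.2 −0.06 and −0.05. Of 100 splits of the infected and control labels within cultivar and day, the real one included, 4 gave 817 genes or more (highest other 4307), which excludes chance at 5% taken alone but not when adjusted by the Benjamini-Hochberg method over the 4 comparisons with 100 splits (0.0533). A split with several times the real count points to a structure of the libraries other than the labels. Without day 24, 86 genes passed.

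MELO3C028362.2 was near 0 in infected 86-1 fruit at days 0, 6, 18 and 24 but lower in controls at day 12, and an exchange of the labels of 86-1 at day 12 would turn round genes that differ steadily on the other days. Genes were taken if called the same way on at least 3 of the other 4 days and not called the other way on the remaining day. Of 16 such genes, 7 were called the other way at day 12, MELO3C028362.2 among them. The counts were 0 of 5 for day 0, 0 of 9 for day 6, 1 of 12 for day 18 and 0 of 7 for day 24. From those sets the rule drops MELO3C028362.2, because its call at day 12 was opposite, so the sets are not alike. Opposite signs without a call were also common at day 6 (5 of 9 in 86-1, 16 of 24 in Jiashi) and at day 12 in Jiashi (6 of 7, 1 called). However, 1 of the 16, MELO3C025925.2, singled out after its values were seen, was lower in infected fruit at day 12 too (33.0 ± 6.09 FPKM against 82.3 ± 8.59, SD, n = 3, adjusted p = 0.0189), as at days 0, 6 and 24. Calls of day 12 were often opposite to those of day 6 (55, against 11.9 for independent lists) and day 18 (43, against 8), as those of day 24 were (75, against 42.4, and 60, against 29.9), but went with those of day 24 (180 higher at both, against 57.3, and 38 opposite, against 102) and with Jiashi at day 12 (r across genes 0.37, 6 opposite, against 11.1). In both cultivars, infected replicate 2 of day 12 had the most genes at 1 FPKM or more in its group (19080 in Jiashi, 18518 in 86-1). The agreement between cultivars at day 12 is not separated from these libraries. In its column name, 86-1 infected day 12 replicate 1 had the letter A where all other columns had P, and the reason is unknown. An exchange can therefore neither be excluded nor shown. A difference between the fruit lots of each group, present at day 0, stays open and was not tested.

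Infected and control 86-1 libraries differed in 1473 genes at day 0. Without 86-1 control day 0 replicate 1, in which 1 read was worth 1.41 times the median, 1057 genes were called, so that library alone did not account for the difference. Leaving out each of the 6 libraries gave 578 to 1080. The infected libraries had 14868 to 15054 genes at 1 FPKM or more, against 15300 to 17227 in controls. The calls are not separated from that number. With median-ratio scaling, 685 genes were higher and 656 lower in infected fruit, in place of 379 and 1094. A response within the day of inoculation and a difference between the fruit chosen for each treatment stay open and were not tested.

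The number of genes at 1 FPKM or more ranged from 14862 to 23003 among the 12 libraries of day 24. A uniform background, such as genomic DNA, would raise all genes by a like amount of FPKM. The mean level of 3424 genes at 1 to 3 FPKM before day 24 was set against that of 3549 nearly silent genes. The slope was 9.31 (8.76 to 12.6 when 1 library was left out), which argues against a uniform background as the only cause. The nearly silent genes were those under 0.5 FPKM in every earlier library, so genes prone to background may be missing from them. Their mean still ranged from 0.030 to 0.729 FPKM among the 12 libraries, so background as a part was not excluded. For shallower libraries, the Spearman correlation with what 1 read was worth was 0.31 (permutation p = 0.331). Pearson's r was 0.55 (permutation p = 0.0381), or 0.12 without the 2 libraries farthest from the median, so a part for depth stays open. Libraries of like depth still differed. In Jiashi infected replicates 1 and 3, 1 read was worth 3.14 times the median, with 21611 and 21548 genes. In Jiashi control replicates 1 and 2 it was worth 3.36 times, with 14862 and 15921. Jiashi control replicate 3 was shallowest, at 7.21, yet had 25021 genes above 0, against 18775 and 20907 in replicates 1 and 2. These values argue against depth as the only cause in Jiashi. The mean number was 2429 higher in infected than in control libraries in Jiashi and −2448 in 86-1 (exact p = 1 for a common difference and 0.165 for a difference between cultivars, 400 relabelings), which leaves infection open as well.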

How the results depend on the processing

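The alternatives without day 24, without day 12 and without the 2 libraries apart (Jiashi control day 24 replicate 3 and 86-1 control day 24 replicate 2) were chosen after the results were seen. Counts stayed within 1.5 times in 16 of 16 comparisons with median-ratio scaling and in 15 of 16 with the pseudocount of 0.1, where Jiashi day 6 gave 5 genes. They did so in 15 of 16 with no filter (Jiashi day 6, 49) and in 14 of 16 with a mean of at least 5 FPKM (Jiashi day 6, 8, and 86-1 day 24, 2317, with fewer genes tested). All 24 named genes kept direction and call in these fits. Gene lists gave no value under any alternative because they were void, and the camera test with an estimated correlation was not run.

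In fits of only the groups compared, Jiashi gave 2 genes at day 0, 0 at day 6, 0 at day 12, 5147 at day 18, 2526 at day 24 and 2122 for the mean, and 86-1 gave 56 at day 6, 200 at day 12, 3 at day 18, 0 at day 24 and 395 for the mean. Storage gave 6953 in Jiashi and 4891 in 86-1. The cause was not tested. With library weights Jiashi gave 1933, 9339, 9827 and 15148 genes at days 0, 6, 18 and 24 and 12046 for the mean, 86-1 gave 6828, 7980, 4714, 6106 and 10437 at days 0 to 24 and 7004 for the mean, the difference of responses 11370 and the cultivars 11798. Weights ran from 0.0506 to 5.98 and were estimated from 3 libraries a group. In the simulated Jiashi mean with the observed spread, weights gave 14 false calls, against 66 without them. They recovered 91.0% of genes changed by 1 log2 unit, against 95.5%. The simulated spread differed by group and not by library, so this does not show whether the weighted counts of the real data hold. The cause of the higher counts was not tested.

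Without day 24 the counts were 258 (Jiashi mean), 101 (86-1 mean), 86 (difference of responses) and 6514 (storage in 86-1 to day 18). Of the 24 named genes, 13 kept their call, 10 lost it, and MELO3C035520.2 reversed to 0.60 log2 units. Without the libraries apart, counts rose to 12982 (Jiashi day 24), 9016 (Jiashi mean), 10099 (86-1 day 24), 2576 (86-1 mean) and 7158 (difference of responses). At day 24 the controls then left had 14862 and 15921 genes at 1 FPKM or more in Jiashi, against 17913 to 21611 in infected libraries. In 86-1 they had 19305 and 20853, against 15734 to 16313. Treatment then coincided with the number of genes detected, in opposite directions in each cultivar, so the higher counts are not separated from it. Without day 12 the difference of responses gave 1309 genes and MELO3C010323.2 lost its call at a difference of 1.96 log2 units (adjusted p = 0.134, from 0.00076 to 0.134 over 10 alternatives). These changes go with the libraries left out, and the cause was not tested.

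With the replicate number as a block within each cultivar, 15 of 16 counts stayed within 1.5 times. The other count, 3908 genes for the cultivars, came from a fit that compared the cultivars at unlike replicate numbers. It does not show how that count depends on the block. Same-numbered infected and control libraries deviated together (r over 0.1) in 15 of 30 pairs, with r from −0.49 to 0.56, and in 11 of 30 the deviation was closest to that of the same number, where chance alone gives 10. At 86-1 day 24 all 3 were (r 0.14, 0.31 and 0.25), so pairing was not shown over all groups and stays open for that one.

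When each library was left out in turn, Jiashi ranged from 66 to 352 genes at day 0, 2 to 1757 at day 6 (the highest without control replicate 1), 38 to 878 at day 12, 1727 to 2469 at day 18, 5313 to 12331 at day 24 and 2603 to 7934 for the mean. In 86-1 the ranges were 578 to 1080 at day 0, 113 to 603 at day 6, 418 to 1027 at day 12, 48 to 569 at day 18, 1600 to 8605 at day 24 and 299 to 1970 for the mean. The difference of responses ranged from 585 to 4019, storage from 9398 to 11869 in Jiashi and 8473 to 11477 in 86-1, and the cultivars from 6143 to 7200. Of the day comparisons, counts moved by over 1.5 times in Jiashi at day 0 without each library but control replicate 3, at day 6 without each of the 6, at day 12 without each but control replicate 1, at day 18 without infected replicate 1 (1727), control replicate 2 (1924) or 3 (1776), and at day 24 without control replicate 3. In 86-1 they did so at day 0 without infected replicate 1 (624) or 2 (578) or control replicate 3 (677), at day 6 without each but control replicate 3, at day 12 without infected replicate 1 (713) or 3 (538) or control replicate 1 (479) or 2 (418), at day 18 without each of the 6, and at day 24 without each but infected replicate 1. Of the named genes, MELO3C007438.2 lost its call in 11 of 24 such fits (log2 −1.36 to −0.94 over the 24) and MELO3C018657.2 in 7 of 24 (−2.52 to −1.56). Depth limits low values most at day 24, where 1 read was worth up to 7.21 times the median.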

Other observations

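The test of a shared response was chosen after the result was seen, and so were the adjustments over the 3 correlation tests and over the splits. Across 23942 genes, which are not independent replicates, the infection responses of Jiashi and 86-1 over days 6 to 24 correlated at 0.12. Redrawing infected and control labels within day in both cultivars 99 times gave −0.63 to 0.48 (one-sided permutation p = 0.31). A response shared by both cultivars is thus neither shown nor excluded by this measure. The rule written for this test would have counted a p above 0.05 against a shared response, but redrawn labels spread too widely for that, and the reading was changed after the result was seen.

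A hypothesis was that infection may move genes the way storage does. It was tested between cultivars, so that no library was shared, over days 6 to 18. The infection response in 86-1 correlated across genes with the change from day 0 to day 18 in Jiashi controls at 0.17, and 99 redrawn sets of 86-1 labels gave −0.18 to 0.18 (one-sided permutation p = 0.02, or 0.03 with median-ratio scaling, where 0.01 is the smallest possible). The response in Jiashi correlated with the storage change in 86-1 controls at 0.062, within the −0.32 to 0.35 of redrawn labels (p = 0.38). Adjusted by the Benjamini-Hochberg method over the 3 correlation tests of this part, the p of 0.02 became 0.06, which misses 0.05, and the others became 0.38. The correlation in 86-1 passed the rule set before the result was seen but failed this correction, so it may be chance. For Jiashi, the rule set beforehand would have counted a permutation p of 0.38 against the hypothesis. That rule was wrong, because redrawn labels from −0.32 to 0.35 could not exclude a correlation of the size seen in 86-1, so the hypothesis stays open there, a reading made after the result.

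Other splits of the same libraries were counted for each comparison. For the mean response in Jiashi, 8 of 100 splits within day, the real one included here and below, called 3408 genes or more (highest other 6788), so chance could not be excluded for that count. For the mean in 86-1 it was 1 of 100 (606, highest other 603), and for the cultivars 1 of 100 (6589, highest other 2583). A random split of these libraries could thus be excluded at 5% for both, also when adjusted over the 4 comparisons with 100 splits (0.02 for each). In 86-1 the margin was narrow, and leaving out 1 library moved the count to between 299 and 1970. Splits of libraries cannot exclude a chance difference between the fruit lots of each group.

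For the comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 5%. In Jiashi, the real count and the highest other were 178 and 54 at day 0, 17 and 3326 at day 6, 470 and 440 at day 12, 3170 and 0 at day 18, and 7673 and 10406 at day 24. At days 6 and 24, 2 of the 10 splits gave as many genes, and the split with 3326 genes points to a structure of the day 6 libraries other than the treatment. In 86-1 they were 1473 and 18 at day 0, 471 and 32 at day 6, 1153 and 0 at day 12, 341 and 2 at day 18, and 4235 and 3065 at day 24. For storage they were 10530 and 4044 in Jiashi and 10150 and 4081 in 86-1. In each of these other comparisons, 1 of the 10 splits, the real one, gave as many.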
